A study of Homo sapiens with 15 samples.

How the data were processed

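RNA from 15 libraries of human adipocytes, grown from subcutaneous adipose progenitor cells, had been sequenced in 4 groups named EV (empty vector, n = 4), Gd6 (LINC00473 overexpression, n = 3), Gd6-Scrambled (n = 4) and Gd6-siRNA (n = 4). Per the labels, total RNA was isolated with a phenol-based reagent, stranded mRNA libraries were made from all samples at the same time, and bcl2fastq and RSEM (versions not given) were run against genome build hg19. The labels give no library batch, aligner, annotation release or strand setting. The deposited values are TPM, transcript abundance scaled by the authors to the same total in every library, for 25807 gene symbols of RefSeq, and each library's column was checked to add up to between 999999 and 1e+06. The numbers of reads are not given, so the depth of each library and the counting error of each value are unknown, and no interval or floor was computed. Between 15183 and 19102 genes were above 0 per library.

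All 15 columns of values were matched to a sample, and groups were taken from the labels. To keep sex-linked expression out of every table, 81 symbols (XIST and Y-linked genes) were left out. Genes with a mean of at least 1 TPM over all libraries were tested, and LINC00473 was tested whatever its level, which gave 12896 genes. Values were used as log2(TPM + 1). One linear model with a mean for each of the 4 groups was fitted per gene with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, two-sided), and p-values were adjusted by Benjamini and Hochberg over the genes tested. A gene was called when its adjusted p was under 0.05. The comparisons were Gd6 minus EV, Gd6-siRNA minus Gd6-Scrambled, Gd6-Scrambled minus Gd6, and the difference between the first and second of these. Replicate numbers were not used as pairs, since no protocol pairs them. For LINC00473 an exact permutation test of the mean log2(TPM + 1) was added. Calls shared by the overexpression and siRNA comparisons, which have no library in common, were tested with Fisher's exact test.

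The tests, alternatives, 28 gene lists and the rule for named genes were fixed before the data were examined. The lists were adipocyte identity, thermogenic (brown and beige) adipocyte, cAMP and CREB-responsive, lipolysis and lipid droplet, fatty acid and triglyceride synthesis, cholesterol synthesis, fatty acid oxidation, nuclear-encoded oxidative phosphorylation, tricarboxylic acid cycle and pyruvate, mitochondrial biogenesis and dynamics, mitochondrially encoded, glycolysis and glucose uptake, insulin signalling, adipose progenitor and fibroblast, collagen and extracellular matrix, smooth muscle and actin cytoskeleton, endothelial cell, macrophage and leukocyte, type I interferon response, inflammatory (NF-kB), unfolded protein response, integrated stress response, p53 response, cell cycle, hypoxia response, NRF2 antioxidant response, genes next to LINC00473 at 6q27, and small RNA silencing machinery. Of their 636 different genes 623 were found in the table, 23 of them under an older symbol, and 27 lists had at least 2 tested genes. Members called higher or lower were counted with p-values adjusted over all genes and adjusted over the list alone. Each list was compared with all other genes with camera of limma (inter-gene correlation preset to 0.01), adjusted over the lists of a comparison, and again with an estimated correlation. Medians of lists are given relative to the median of all genes.

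Named genes were LINC00473, the 10 largest rises and 10 largest falls of the overexpression and siRNA comparisons, the 5 of each for Gd6-Scrambled minus Gd6 and for genes changed in opposite directions, and up to 4 members per list with the smallest adjusted p. The largest changes were taken among called genes whose groups did not overlap in the comparison ranked (Gd6 against EV for opposite changes) and whose mean was at least 5 TPM. Genes given with values outside this rule, which were UCP1, PPARGC1A, CPT1A, LPL, ADIPOQ and MIR616 where the rule did not name them, and list members in counts of 5 or fewer were chosen after their values were seen. Some genes that the rule or a list would name are not reported here.

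Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of at least 5 TPM, median-of-ratios scaling (size factors 0.828 to 1.22), quantile normalization, a fit of only the groups compared, no trend, array weights, a replicate block, camera with an estimated correlation, and each library left out in turn. The pipeline was tested on simulated data with 200 changed genes of 12896. Simulated genes varied independently of each other, with no shift common to all genes. The shares recovered and false therefore need not hold for the real data. A log2 change of 1 was recovered for 92.5% of genes in the overexpression comparison, 95.5% in the siRNA comparison, 82.1% in Gd6-Scrambled minus Gd6 and 82.1% in the difference, and 1.2%, 5.49%, 3.75% and 5.33% of calls were false. Correlations of log2 values were 0.9795 to 0.9937 within groups and at most 0.9829 between groups.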

Results

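RNA was sequenced from 15 libraries of adipocytes grown from human subcutaneous adipose progenitor cells, and the deposited table gives TPM, transcript abundance scaled to the same total in every library, for each RefSeq gene symbol. The libraries fall into 4 groups. EV (n = 4) carried an empty vector and Gd6 (n = 3, replicates 2 to 4) overexpressed LINC00473, a long non-coding RNA encoded at 6q27. Gd6-Scrambled (n = 4) and Gd6-siRNA (n = 4) carry the Gd6 label together with a scrambled control siRNA or an siRNA against LINC00473. The labels do not explain the name Gd6, and they do not say whether libraries of a group came from separate cultures or donors, so the p-values measure only the spread between these samples. Sequencing depth is unknown because TPM values keep none of it. Between 15183 genes (Gd6 replicate 3) and 19102 genes (Gd6-Scrambled replicate 1) were above 0 per library, and 12896 genes were tested. TPM values are means ± SD over the libraries of a group, and log2 changes of TPM + 1 are given ± SE. Medians of gene lists are medians of log2 changes minus the median of all genes.

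LINC00473 was listed at 0 in all 4 EV libraries. It was present in every Gd6 library, at 3.04, 4.23 and 1.83 TPM in replicates 2, 3 and 4 (mean 3.03 ± 1.2 TPM, n = 3). All 3 Gd6 libraries therefore lay above all 4 EV libraries, which gave the smallest p that the 35 arrangements allow (two-sided exact permutation test, p = 0.057). In limma the log2 change of LINC00473 from EV to Gd6 was 1.97 ± 1.05 with an adjusted p of 0.15, so overexpression did not pass the threshold when all 15 libraries shared one estimate of the spread. Without Gd6-Scrambled replicate 3 the same change of 1.97 had an adjusted p of 2.3e-06.

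In the Gd6-Scrambled group LINC00473 stood at 2.85, 3.19, 244.98 and 3.06 TPM in replicates 1 to 4, so that 1 library held the gene far above the other 3 (mean 63.5 ± 121 TPM, n = 4, and 3.03 ± 0.172 TPM without replicate 3). The siRNA libraries held 1.24, 0.56, 0.68 and 0.92 TPM (mean 0.85 ± 0.3 TPM, n = 4). LINC00473 was lower in all 4 Gd6-siRNA libraries than in any Gd6-Scrambled library, the most extreme of the 70 arrangements (two-sided exact permutation test, p = 0.029). The limma log2 change was -2.62 ± 0.97 (adjusted p = 0.035). The Gd6-siRNA mean was 98.7% below the Gd6-Scrambled mean, and 71.9% below it without Gd6-Scrambled replicate 3, where the log2 change was -1.14 (adjusted p = 0.00017). Leaving out a Gd6-siRNA library ended the limma call, with -2.72 (adjusted p = 0.05) without replicate 1, -2.54 (adjusted p = 0.064) without replicate 2, -2.58 (adjusted p = 0.068) without replicate 3 and -2.64 (adjusted p = 0.058) without replicate 4. From Gd6 to Gd6-Scrambled the change of LINC00473 was 1.53 ± 1.05 (adjusted p = 0.28, two-sided exact permutation p = 0.46), with medians of 3.04 and 3.12 TPM. LINC00473 overlaps the PDE10A region in the current RefSeq annotation, and the strand setting of the deposited values is not given.

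**Figure D1:**
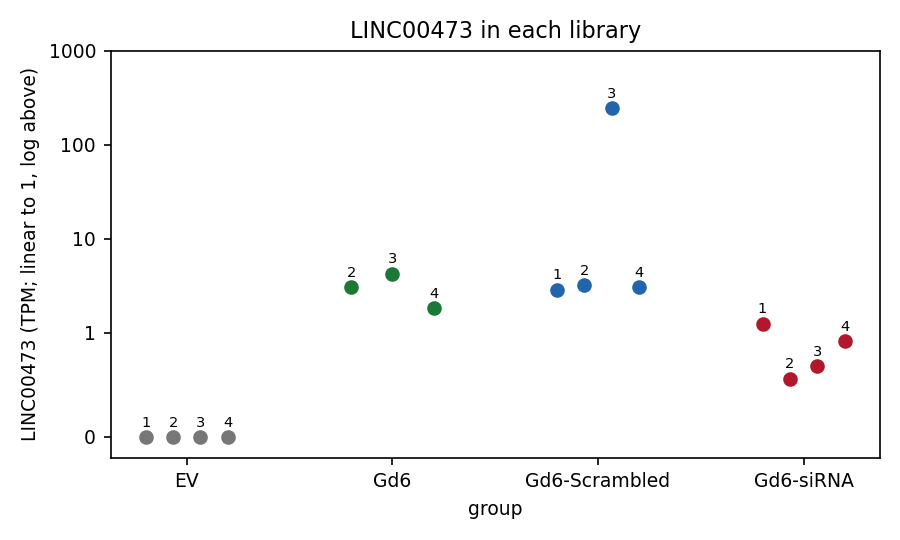
LINC00473 in TPM (vertical axis, linear up to 1 and logarithmic above) in each of the 15 libraries by group, each point 1 library with its replicate number. The 4 EV libraries lie at 0, the Gd6 libraries between 1.83 and 4.23 TPM, Gd6-Scrambled replicate 3 at 244.98 TPM above the 2.85 to 3.19 TPM of its group, and the Gd6-siRNA libraries between 0.56 and 1.24 TPM.

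The comparison of Gd6 with EV asks how the adipocyte transcriptome differs when LINC00473 is overexpressed. Gd6 libraries held more mRNA of adipocyte, lipid-handling and mitochondrial genes and less mRNA of interferon-induced, matrix and fibroblast genes than EV libraries. With an estimated correlation the interferon, matrix, progenitor, synthesis and biogenesis lists lost their calls (adjusted p = 0.2, 0.2, 0.22, 0.2 and 0.2). ADIPOQ, which encodes the adipocyte hormone adiponectin, rose from 3407 ± 295 to 8227 ± 368 TPM (log2 change 1.27 ± 0.12, adjusted p = 1.03e-06). LIPE, which encodes hormone-sensitive lipase, rose from 281 ± 25.8 to 692 ± 24.1 TPM (log2 change 1.30 ± 0.092, adjusted p = 1.36e-07). Among 77 nuclear genes of the respiratory chain and ATP synthase, 66 rose and 1 fell. All but 1 of 29 type I interferon response genes fell. Over all 12896 genes, 1494 rose and 3658 fell, and 157 of the former and 211 of the latter changed at least 2-fold.

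Adipocyte identity genes rose as a group. Of the adipocyte identity list, 19 of 27 tested genes rose, 1 fell and 7 were not called (20 and 1 adjusted over the list alone). Adipocyte identity genes had a median of 0.76 (camera adjusted p = 4.9e-14, and 0.035 with an estimated correlation). The adipogenesis regulatory factor gene ADIRF rose from 228 ± 20.5 to 838 ± 86.3 TPM (log2 change 1.87 ± 0.11, adjusted p = 2.92e-08). PCK1, an enzyme of glyceroneogenesis in fat cells, rose from 43.7 ± 8.74 to 243 ± 20.9 TPM (log2 change 2.46 ± 0.15, adjusted p = 2.99e-08). For the lipolysis and lipid droplet list, 16 of 24 tested genes rose, 4 fell and 4 were not called (16 and 4 adjusted over the list alone). Lipolysis genes had a median of 0.57 (camera adjusted p = 5.9e-08, and 0.026 with an estimated correlation). CIDEC, which acts in lipid droplet growth, rose from 1755 ± 142 to 2982 ± 56.7 TPM (log2 change 0.77 ± 0.065, adjusted p = 6.1e-07). In the fatty acid and triglyceride synthesis list, 11 of 22 tested genes rose, 4 fell and 7 were not called (12 and 4 adjusted over the list alone). Synthesis genes had a median of 0.42 (camera adjusted p = 3.8e-05, and 0.2 with an estimated correlation). DGAT2, which catalyses the last step of triglyceride synthesis, rose from 1371 ± 115 to 2841 ± 115 TPM (log2 change 1.05 ± 0.089, adjusted p = 5.51e-07).

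Mitochondrial genes rose with them. In the nuclear-encoded oxidative phosphorylation list, 66 of 77 tested genes rose, 1 fell and 10 were not called (66 and 1 adjusted over the list alone). Oxidative phosphorylation genes had a median of 0.65 (camera adjusted p = 7.7e-36, and 0.0035 with an estimated correlation). SDHA, a subunit of complex II, rose from 113 ± 2.12 to 207 ± 7.9 TPM (log2 change 0.86 ± 0.052, adjusted p = 3.36e-08). Of the tricarboxylic acid cycle and pyruvate list, 20 of 25 tested genes rose, 0 fell and 5 were not called (21 and 0 adjusted over the list alone). Cycle genes had a median of 0.57 (camera adjusted p = 5.8e-16, and 0.025 with an estimated correlation). The citrate synthase gene CS rose from 516 ± 12.5 to 874 ± 48.3 TPM (log2 change 0.76 ± 0.063, adjusted p = 5.17e-07). For fatty acid oxidation, 19 of 24 tested genes rose, 2 fell and 3 were not called (19 and 3 adjusted over the list alone). Oxidation genes had a median of 0.74 (camera adjusted p = 2.7e-13, and 0.018 with an estimated correlation). Of the beta-oxidation enzymes, ACAA2 rose from 375 ± 22.3 to 654 ± 4.23 TPM (log2 change 0.80 ± 0.059, adjusted p = 1.79e-07). Mitochondrial biogenesis and dynamics genes moved less, as 8 of 25 tested genes rose, 1 fell and 16 were not called (8 and 1 adjusted over the list alone). Biogenesis genes had a median of 0.15 (camera adjusted p = 0.007, and 0.2 with an estimated correlation). The mitochondrially encoded list could not be tested, since 0 of its 13 genes are in the file.

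Glucose and insulin genes showed smaller shifts. In the glycolysis and glucose uptake list, 9 of 23 tested genes rose, 3 fell and 11 were not called (9 and 3 adjusted over the list alone). Glycolysis genes had a median of 0.22 (camera adjusted p = 0.00062, and 0.3 with an estimated correlation). SLC2A4, the insulin-responsive glucose transporter, rose from 10.8 ± 1.43 to 23 ± 2.43 TPM (log2 change 1.03 ± 0.11, adjusted p = 3.79e-06). For insulin signalling, 7 of 21 tested genes rose, 4 fell and 10 were not called (10 and 4 adjusted over the list alone). Insulin genes had a median of 0.16 (camera adjusted p = 0.025, and 0.48 with an estimated correlation). The thermogenic adipocyte list moved both ways, with 5 genes higher and 6 lower of 15 tested (5 and 6 adjusted over the list alone, camera adjusted p = 0.5). UCP1, the uncoupling protein of brown and beige fat, fell from 4.31 ± 1.87 to 0.62 ± 0.238 TPM (log2 change -1.64 ± 0.29, adjusted p = 0.000373), while PPARGC1A, a coactivator of mitochondrial gene expression, rose from 24.6 ± 1.71 to 34.8 ± 4.23 TPM (log2 change 0.48 ± 0.095, adjusted p = 0.0011).

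Matrix and progenitor genes fell. Of the adipose progenitor and fibroblast list, 1 of 18 tested genes rose, 12 fell and 5 were not called (1 and 12 adjusted over the list alone). Progenitor and fibroblast genes had a median of -0.55 (camera adjusted p = 0.0014, and 0.22 with an estimated correlation). DCN, which encodes the proteoglycan decorin, fell from 647 ± 23.7 to 269 ± 12.3 TPM (log2 change -1.27 ± 0.095, adjusted p = 2.3e-07). PDGFRB, a growth factor receptor of mesenchymal cells, fell from 357 ± 39.2 to 190 ± 16.6 TPM (log2 change -0.91 ± 0.11, adjusted p = 1.33e-05). In the collagen and extracellular matrix list, 5 of 31 tested genes rose, 23 fell and 3 were not called (5 and 23 adjusted over the list alone). Matrix genes had a median of -0.45 (camera adjusted p = 3.8e-05, and 0.2 with an estimated correlation). MMP2, a matrix metalloproteinase, fell from 1070 ± 37.7 to 426 ± 29 TPM (log2 change -1.33 ± 0.059, adjusted p = 2.94e-09). The smooth muscle and actin cytoskeleton list had 4 genes higher and 10 lower of 17 tested (4 and 10 adjusted over the list alone, camera adjusted p = 0.65). Few markers of other cell types were tested. The endothelial cell list had 0 genes higher and 1 lower of 2 tested (0 and 2 adjusted over the list alone, camera adjusted p = 0.53), and the macrophage and leukocyte list had 1 gene higher and 2 lower of 4 tested (1 and 2 adjusted over the list alone, camera adjusted p = 0.99).

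Type I interferon response genes fell, as 28 of 29 tested did, 0 rose and 1 was not called (29 fell and 0 rose adjusted over the list alone). Interferon genes had a median of -1.55 (camera adjusted p = 4.9e-14, and 0.2 with an estimated correlation). IRF9, a subunit of the transcription factor that interferon activates, fell from 43.5 ± 5.41 to 19.2 ± 1.2 TPM (log2 change -1.13 ± 0.085, adjusted p = 2.17e-07). The interferon-induced genes MX1 and IFI44L fell as well, from 51.3 ± 20.4 to 5.41 ± 1.94 TPM (log2 change -2.96 ± 0.33, adjusted p = 7.27e-06) and from 23.7 ± 6.62 to 2.36 ± 0.658 TPM (log2 change -2.86 ± 0.25, adjusted p = 7.69e-07). For the inflammatory (NF-kB) list, 2 of 22 tested genes rose, 14 fell and 6 were not called (3 and 16 adjusted over the list alone). Inflammatory genes had a median of -0.36 (camera adjusted p = 0.027, and 0.45 with an estimated correlation).

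Stress response lists moved in different directions. Unfolded protein response genes fell, as 10 of 16 tested did, 0 rose and 6 were not called (10 fell and 0 rose adjusted over the list alone). The list had a median of -0.36 (camera adjusted p = 0.00089, and 0.018 with an estimated correlation). HSPA5, the endoplasmic reticulum chaperone BiP, fell from 406 ± 5.18 to 251 ± 7.62 TPM (log2 change -0.69 ± 0.053, adjusted p = 2.48e-07). Integrated stress response genes rose, as 14 of 22 tested did, 1 fell and 7 were not called (14 and 2 adjusted over the list alone). This list had a median of 0.49 (camera adjusted p = 8e-07, and 0.018 with an estimated correlation). TRIB3, a pseudokinase induced by ATF4, rose from 25.2 ± 4.39 to 63.1 ± 8.64 TPM (log2 change 1.30 ± 0.12, adjusted p = 1.02e-06). In the NRF2 antioxidant response list, 1 of 17 tested genes rose, 11 fell and 5 were not called (1 and 15 adjusted over the list alone). NRF2 genes had a median of -0.45 (camera adjusted p = 2.8e-05, and 0.018 with an estimated correlation). HMOX1, heme oxygenase 1, fell from 254 ± 9.61 to 170 ± 3.29 TPM (log2 change -0.57 ± 0.049, adjusted p = 6.51e-07).

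The other lists were not called in this comparison. The cAMP and CREB-responsive list had 2 genes higher and 11 lower of 19 tested (2 and 12 adjusted over the list alone, camera adjusted p = 0.12), and after median-of-ratios scaling it was called lower (camera adjusted p = 0.038). Cholesterol synthesis had 4 genes higher and 6 lower of 25 tested (4 and 6 adjusted over the list alone, camera adjusted p = 0.55). For p53 response the counts were 3 genes higher and 6 lower of 17 tested (3 and 6 adjusted over the list alone, camera adjusted p = 0.99). Cell cycle had 1 gene higher and 4 lower of 22 tested (1 and 4 adjusted over the list alone, camera adjusted p = 0.65), and hypoxia response had 3 genes higher and 5 lower of 16 tested (4 and 5 adjusted over the list alone, camera adjusted p = 0.82). Small RNA silencing machinery had 0 genes higher and 6 lower of 12 tested (1 and 8 adjusted over the list alone, camera adjusted p = 0.2). Genes next to LINC00473 at 6q27 had 1 gene higher and 1 lower of 3 tested (1 and 1 adjusted over the list alone, camera adjusted p = 0.65), and of these MPC1, a subunit of the mitochondrial pyruvate carrier, rose from 41.2 ± 4.61 to 71.9 ± 6.71 TPM (log2 change 0.79 ± 0.10, adjusted p = 2.56e-05), while RPS6KA2 was lower and SFT2D1 was not called.

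Some members went against their list, and these were named after their values were seen. LPL fell among adipocyte identity genes, PLIN3, PRKAR1A, HILPDA and HSD17B11 fell among lipolysis genes, and ACLY, ELOVL6, FADS1 and FADS2 fell among synthesis genes. CPT1A and PDK4 fell in the oxidation list, ATP5G3 in the oxidative phosphorylation list, C10orf2 in the biogenesis list, SLC2A3, HK1 and ENO2 in the glycolysis list, and IGF1R, IGFBP5 and ENPP1 in the insulin list. CD34 rose among progenitor genes, COL15A1, SPARC, LOX, TIMP3 and THBS1 rose among matrix genes, SAA1 and SAA2 among inflammatory genes and TALDO1 among NRF2 genes. PSPH fell in the integrated stress response list, and RSAD2 was the interferon gene not called. In lists that were not called, PER1 and PPARGC1A (cAMP), MVK, PMVK, TM7SF2 and DHCR7 (cholesterol), TP53I3, BBC3 and GDF15 (p53), PLK1 (cell cycle), PDK1, HK2 and LOX (hypoxia), TAGLN, CSPG4, CYR61 and CTGF (smooth muscle) and CD14 (leukocyte) rose. CCNB1, CDC6, MCM6 and FOXM1 (cell cycle), CA12, ADM, P4HA1, P4HA2 and HILPDA (hypoxia), CD68 and CD74 (leukocyte) and EGFL7 (endothelial) fell. Of the thermogenic genes, PPARGC1A, PPARGC1B, CKMT1B, KCNK3 and SLC36A2 rose. PRKAR1A, FADS2, ATP5G3, C10orf2, HK1, ENO2, EGFL7, PSPH, MCM6 and ADM were no longer called after median-of-ratios scaling or quantile normalization.

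By the rule for the largest changes, the metallothionein gene MT1F rose from 4.88 ± 2.09 to 67.2 ± 15.2 TPM (log2 change 3.57 ± 0.24, adjusted p = 9.43e-08). The organic anion transporter gene SLCO2B1 rose from 1.26 ± 0.238 to 12 ± 1.52 TPM (log2 change 2.52 ± 0.12, adjusted p = 3.15e-09), and the complement gene C6 rose from 51.9 ± 3.5 to 298 ± 20.9 TPM (log2 change 2.50 ± 0.11, adjusted p = 2.94e-09). Next came PCK1, UGT1A6, LTF, MT1X, CHIA and SLC25A18, of which LTF (lactoferrin) and CHIA (acidic chitinase) encode secreted proteins. LTF rose from 6.79 ± 0.875 to 36.9 ± 8.64 TPM, and CHIA rose from 83.3 ± 6.27 to 340 ± 21.5 TPM. The largest falls were in CHI3L1, a chitinase-like secreted protein, which fell from 18.5 ± 2.75 to 0.513 ± 0.0321 TPM (log2 change -3.68 ± 0.17, adjusted p = 3.15e-09), and in IFITM1, which fell from 113 ± 35.3 to 9.41 ± 2.08 TPM (log2 change -3.42 ± 0.28, adjusted p = 3.75e-07). PRG4, which encodes lubricin, fell from 178 ± 16.4 to 21.2 ± 2.11 TPM (log2 change -3.01 ± 0.14, adjusted p = 3.15e-09). MX1, IFI44L, IFI27, IFIT3, OLFML2B, MX2 and IFI6 completed the list, and 6 of these 7 are interferon-induced genes. For each of these 19 genes every Gd6 library lay on one side of every EV library. MT1F, MT1X, UGT1A6 and IFITM1 have close paralogs or shared exons, so their values are uncertain as to the family member.

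Gd6 and EV values did not overlap for 5471 of the tested genes (42.4%, where chance gives 5.71%). The median change of all genes was -0.118, and after median-of-ratios scaling it was -0.002 and the split was 2274 higher and 2113 lower (2052 and 2279 after quantile normalization). The inflammatory list's call ended without EV replicate 1 (adjusted p = 0.06), without Gd6 replicate 2 (adjusted p = 0.065), at a pseudocount of 5 (adjusted p = 0.079) and with array weights (adjusted p = 0.055). Without a filter the cAMP and small RNA silencing lists were called lower (adjusted p = 0.022 and 0.032). In lists where the balance of members called turned or a count moved by at least 5 under either scaling, the members higher/lower after median-of-ratios scaling and after quantile normalization were 5/5 and 5/5 (thermogenic), 6/4 and 5/5 (cholesterol), 0/0 and 0/0 (endothelial), 5/3 and 5/4 (p53), 3/4 and 3/3 (cell cycle), 6/4 and 6/5 (hypoxia) and 1/1 and 1/1 (small RNA silencing).

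The comparison of Gd6-siRNA with Gd6-Scrambled asks how the transcriptome differs when LINC00473 is reduced in cells with the Gd6 label. Adipocyte, lipid-handling and mitochondrial genes were lower with the LINC00473 siRNA, and genes of the progenitor, stress and inflammatory lists were higher. With an estimated correlation the progenitor, inflammatory, synthesis and biogenesis lists lost their calls (adjusted p = 0.34, 0.34, 0.22 and 0.27). ADIPOQ fell from 5776 ± 600 to 1193 ± 207 TPM (log2 change -2.28 ± 0.11, adjusted p = 1.11e-09). RBP4, a retinol-binding protein secreted by fat, fell from 214 ± 14.4 to 12.4 ± 3.57 TPM (log2 change -4.05 ± 0.16, adjusted p = 2.89e-10). None of the 77 oxidative phosphorylation genes rose and 72 fell. Over all genes tested, 5009 rose and 1670 fell, 339 and 228 of them at least 2-fold.

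In the adipocyte identity list, 0 of 27 tested genes rose, 24 fell and 3 were not called (0 and 25 adjusted over the list alone). Adipocyte identity genes had a median of -1.03 (camera adjusted p = 1e-21, and 0.014 with an estimated correlation). GPD1 fell from 1988 ± 91.4 to 762 ± 37.5 TPM (log2 change -1.38 ± 0.052, adjusted p = 1.96e-10). The 3 members not called were LPL, CD36 and PDE3B. Of the lipolysis and lipid droplet list, 2 of 24 tested genes rose, 15 fell and 7 were not called (3 and 16 adjusted over the list alone). Lipolysis genes had a median of -0.70 (camera adjusted p = 6.3e-10, and 0.014 with an estimated correlation). CIDEC fell from 2250 ± 98 to 948 ± 52.9 TPM (log2 change -1.25 ± 0.060, adjusted p = 1.4e-09), and LIPE fell from 570 ± 44.6 to 243 ± 26.4 TPM (log2 change -1.23 ± 0.085, adjusted p = 3.83e-08). For fatty acid and triglyceride synthesis, 6 of 22 tested genes rose, 11 fell and 5 were not called (7 and 11 adjusted over the list alone). Synthesis genes had a median of -0.45 (camera adjusted p = 5.9e-05, and 0.22 with an estimated correlation). The thermogenic list had 3 genes higher and 6 lower of 15 tested (3 and 6 adjusted over the list alone, camera adjusted p = 0.0048), and adjusted p = 0.084 with an estimated correlation. PPARGC1A fell from 39.9 ± 2.41 to 28.4 ± 3.23 TPM (log2 change -0.48 ± 0.088, adjusted p = 0.00036) and SLC36A2, an amino acid transporter of brown fat, fell from 3.42 ± 0.467 to 0.285 ± 0.11 TPM (log2 change -1.78 ± 0.13, adjusted p = 5.36e-08).

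Most mitochondrial lists fell. For the nuclear-encoded oxidative phosphorylation list, 0 of 77 tested genes rose, 72 fell and 5 were not called (0 and 73 adjusted over the list alone). Oxidative phosphorylation genes had a median of -0.75 (camera adjusted p = 3.8e-39, and 0.0024 with an estimated correlation). COX6A1, a subunit of complex IV, fell from 1319 ± 86.8 to 583 ± 51.9 TPM (log2 change -1.18 ± 0.065, adjusted p = 4.8e-09). Of the tricarboxylic acid cycle and pyruvate list, 0 of 25 tested genes rose, 21 fell and 4 were not called (0 and 23 adjusted over the list alone). Cycle genes had a median of -0.67 (camera adjusted p = 5.6e-17, and 0.019 with an estimated correlation). PDHA1, a subunit of pyruvate dehydrogenase, fell from 133 ± 5.03 to 78.1 ± 3.61 TPM (log2 change -0.76 ± 0.053, adjusted p = 4.19e-08). In the fatty acid oxidation list, 2 of 24 tested genes rose, 20 fell and 2 were not called (2 and 20 adjusted over the list alone). Oxidation genes had a median of -0.88 (camera adjusted p = 1.6e-16, and 0.014 with an estimated correlation). ETFDH, which passes electrons from beta-oxidation to the respiratory chain, fell from 120 ± 5.64 to 52.4 ± 2.78 TPM (log2 change -1.18 ± 0.058, adjusted p = 1.59e-09), while CPT1A, the carnitine palmitoyltransferase of the outer mitochondrial membrane, rose from 22.6 ± 1.65 to 50 ± 3.79 TPM (log2 change 1.11 ± 0.068, adjusted p = 1.27e-08). For mitochondrial biogenesis and dynamics, 6 of 25 tested genes rose, 8 fell and 11 were not called (7 and 8 adjusted over the list alone). Biogenesis genes had a median of -0.25 (camera adjusted p = 0.012, and 0.27 with an estimated correlation). In glycolysis and glucose uptake, 4 of 23 tested genes rose, 11 fell and 8 were not called (4 and 11 adjusted over the list alone). Glycolysis genes had a median of -0.32 (camera adjusted p = 0.0014, and 0.34 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.094). Insulin signalling genes moved both ways, as 4 of 21 tested genes rose, 7 fell and 10 were not called (4 and 7 adjusted over the list alone). Insulin genes had a median of -0.19 (camera adjusted p = 0.012, and 0.42 with an estimated correlation).

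**Figure D2:**
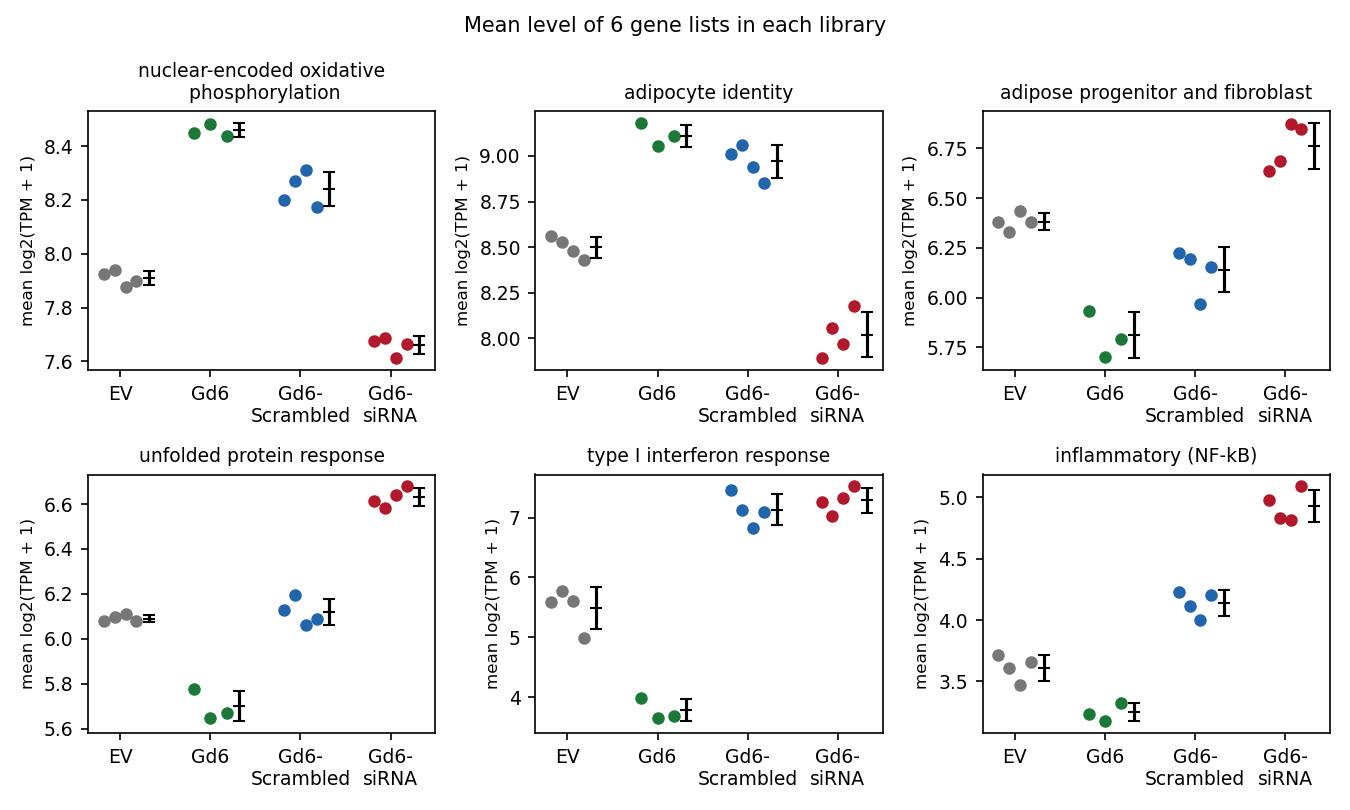
Mean log2(TPM + 1) of 6 gene lists in each library (points, by group) with the group mean ± SD (black bar). The oxidative phosphorylation level was 7.91 ± 0.027 in EV (n = 4), 8.46 ± 0.025 in Gd6 (n = 3), 8.24 ± 0.064 in Gd6-Scrambled (n = 4) and 7.66 ± 0.033 in Gd6-siRNA (n = 4), and the interferon level was lowest in Gd6, at 3.78 ± 0.184.

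Progenitor and fibroblast genes rose, as 13 of 18 tested did, 0 fell and 5 were not called (13 and 1 adjusted over the list alone). Progenitor and fibroblast genes had a median of 0.48 (camera adjusted p = 0.0085, and 0.34 with an estimated correlation). Of the surface proteins of mesenchymal cells, ENG rose from 80.7 ± 8.69 to 187 ± 10.6 TPM (log2 change 1.21 ± 0.079, adjusted p = 2.2e-08) and CD44 rose from 190 ± 17.6 to 386 ± 30.1 TPM (log2 change 1.02 ± 0.083, adjusted p = 1.94e-07). The collagen and extracellular matrix list had 19 genes higher and 5 lower of 31 tested (19 and 5 adjusted over the list alone, camera adjusted p = 0.11), and it was called higher without Gd6-siRNA replicate 4 (adjusted p = 0.049) and after quantile normalization (adjusted p = 5e-04). POSTN, a matrix protein named periostin, rose from 12.8 ± 1.57 to 109 ± 21.1 TPM (log2 change 2.97 ± 0.17, adjusted p = 5.51e-09). Smooth muscle genes had 8 genes higher and 4 lower of 17 tested (9 and 4 adjusted over the list alone, camera adjusted p = 0.77), with a median change of 0.15, a mean of 0.09 and a camera direction below that of all genes. The endothelial list had 0 genes higher and 0 lower of 2 tested (0 and 0 adjusted over the list alone, camera adjusted p = 0.73). The macrophage and leukocyte list had 2 genes higher and 0 lower of 4 tested (2 and 0 adjusted over the list alone, camera adjusted p = 0.65).

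Inflammatory (NF-kB) genes rose, as 15 of 22 tested did, 4 fell and 3 were not called (15 and 5 adjusted over the list alone). Inflammatory genes had a median of 0.74 (camera adjusted p = 0.0085, and 0.34 with an estimated correlation). The immediate-early gene IER3 rose from 5.67 ± 0.911 to 37.8 ± 4.92 TPM (log2 change 2.54 ± 0.10, adjusted p = 3.34e-10), and ICAM1, a leukocyte adhesion molecule, rose from 3.98 ± 0.598 to 19.1 ± 3.08 TPM (log2 change 2.01 ± 0.12, adjusted p = 1.29e-08). The type I interferon list was not called, with 6 genes higher and 0 lower of 29 tested (5 and 0 adjusted over the list alone, camera adjusted p = 0.56), and its median minus that of all genes was -0.09 and turned to 0.02 after quantile normalization. For the cAMP and CREB-responsive list, 15 of 19 tested genes rose, 2 fell and 2 were not called (15 and 2 adjusted over the list alone). The cAMP list had a median of 0.37 (camera adjusted p = 0.011, and 0.26 with an estimated correlation). Without a filter the matrix, cell cycle and small RNA silencing lists were called higher (adjusted p = 0.018, 0.014 and 0.01). Calls of the thermogenic, cAMP and inflammatory lists ended among genes of mean TPM of at least 5 (adjusted p = 0.14, 0.095 and 0.13).

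Unfolded protein response genes rose, as 14 of 16 tested did, 0 fell and 2 were not called (14 and 0 adjusted over the list alone). The list had a median of 0.29 (camera adjusted p = 0.00047, and 0.014 with an estimated correlation). HERPUD1, a component of endoplasmic reticulum protein degradation, rose from 53.8 ± 1.07 to 87.1 ± 2.39 TPM (log2 change 0.69 ± 0.051, adjusted p = 7.71e-08). Integrated stress response genes also rose, as 18 of 22 tested did, 0 fell and 4 were not called (21 and 0 adjusted over the list alone). This list had a median of 0.49 (camera adjusted p = 5.1e-07, and 0.014 with an estimated correlation). SLC7A5, an amino acid transporter, rose from 9.9 ± 0.742 to 37.2 ± 1.43 TPM (log2 change 1.81 ± 0.073, adjusted p = 3.34e-10). In the cholesterol synthesis list, 17 of 25 tested genes rose, 2 fell and 6 were not called (18 and 2 adjusted over the list alone). Cholesterol genes had a median of 0.31 (camera adjusted p = 0.011, and 0.39 with an estimated correlation).

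The remaining lists were not called. NRF2 antioxidant response had 9 genes higher and 2 lower of 17 tested (10 and 2 adjusted over the list alone, camera adjusted p = 0.56). For p53 response there were 9 genes higher and 1 lower of 17 tested (9 and 1 adjusted over the list alone, camera adjusted p = 0.56). Cell cycle had 12 genes higher and 2 lower of 22 tested (12 and 2 adjusted over the list alone, camera adjusted p = 0.29). Hypoxia response had 7 genes higher and 4 lower of 16 tested (7 and 4 adjusted over the list alone, camera adjusted p = 0.65), and small RNA silencing machinery had 9 genes higher and 0 lower of 12 tested (9 and 0 adjusted over the list alone, camera adjusted p = 0.077). Genes next to LINC00473 had 0 genes higher and 0 lower of 3 tested (0 and 0 adjusted over the list alone, camera adjusted p = 0.96). MPC1, which was higher in Gd6 than in EV, stood at 70.9 ± 7.77 TPM in Gd6-Scrambled and 70.8 ± 5.11 TPM in Gd6-siRNA (adjusted p = 0.984).

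Members against their list, named after their values were seen, included HILPDA and HSD17B11 (lipolysis), CPT1A and CPT1B (oxidation), SLC2A3, HK1, PFKP and SLC16A3 (glycolysis), PTPN1, PHLDA3 and IGF1R (insulin), PRDM16, EBF2 and CPT1B (thermogenic), all of which rose. PER1 and PPARGC1A (cAMP), PMVK and TM7SF2 (cholesterol) and IL1B, C3, SAA1 and SAA2 (inflammatory) fell. SDF2L1 and CRELD2 were the unfolded protein response genes not called, and DDIT3, CEBPB, NUPR1 and ATF5 the integrated stress response genes not called. In lists without a call, COL3A1, COL5A2, SPARC, TIMP3 and VCAN (matrix), LMOD1, CSPG4, TAGLN and MYL9 (smooth muscle), BTG2 (p53), AURKA and PCNA (cell cycle), CA12, ADM, NDRG1 and HK2 (hypoxia) and NQO1 and TALDO1 (NRF2) fell, and CD68 and CD74 (leukocyte) rose. EBF2, PRDM16, HSD17B11, HILPDA, HK1, PFKP, PTPN1, CD68 and CD74 were no longer called after median-of-ratios scaling or quantile normalization.

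The largest rises by the rule were in POSTN, IER3, SPRY4, WISP1, TMEM171, UNC5B, SPHK1, ITGA2, BHLHE40 and ICAM1. SPRY4, an inhibitor of receptor tyrosine kinase signalling, rose from 4.96 ± 0.64 to 33 ± 6.25 TPM (log2 change 2.50 ± 0.13, adjusted p = 3.26e-09), and ITGA2, a collagen-binding integrin subunit, rose from 7.59 ± 1.01 to 34.3 ± 1.72 TPM (log2 change 2.05 ± 0.089, adjusted p = 6.45e-10). The largest falls were in RBP4, HIST1H4K, PCP4L1, UGT1A6, CHIA, PPP1R1B, LTF, CAMP, REEP6 and LINC00473. LINC00473 is among these 10 through Gd6-Scrambled replicate 3, without which its log2 change was -1.14 and its mean below the 5 TPM of the rule. PCP4L1 fell from 27.4 ± 1.24 to 0.963 ± 0.164 TPM (log2 change -3.86 ± 0.077, adjusted p = 1.91e-13). CHIA fell from 258 ± 23.5 to 23.7 ± 6.05 TPM (log2 change -3.42 ± 0.13, adjusted p = 1.96e-10). LTF and CAMP, the genes of the antimicrobial proteins lactoferrin and cathelicidin, fell as well, from 48.6 ± 1.72 to 5.43 ± 1.17 TPM (log2 change -2.96 ± 0.14, adjusted p = 1.14e-09) and from 16.3 ± 2.66 to 1.54 ± 1.19 TPM (log2 change -2.86 ± 0.22, adjusted p = 1.21e-07). HIST1H4K was listed at 0 in every Gd6-siRNA library and at 14.6 ± 3.45 TPM in Gd6-Scrambled, and as near-identical histone H4 copies share reads this value is uncertain. For each of these 20 genes the libraries of the 2 groups did not overlap.

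Gd6-siRNA and Gd6-Scrambled values did not overlap for 5958 of the tested genes (46.2%, where chance gives 2.86%). The median change of all genes was 0.186, and after median-of-ratios scaling it was 0.004 and the split turned to 2547 higher and 2891 lower (2929 and 2661 after quantile normalization). The members higher/lower after these 2 scalings, given where the balance turned or a count moved by at least 5, were 12/3 and 10/3 (cAMP), 12/4 and 16/2 (cholesterol), 0/14 and 1/11 (biogenesis), 14/11 and 18/5 (matrix), 6/6 and 6/4 (smooth muscle), 0/0 and 1/0 (leukocyte), 9/0 and 14/0 (unfolded protein response) and 2/0 and 2/0 (small RNA silencing).

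The Gd6 and EV libraries share none with the siRNA comparison, so the calls of both comparisons were set against each other. Of the genes raised in Gd6, 815 were lowered with the siRNA, where 193 would be shared by independent lists (odds ratio 14.8, two-sided Fisher's exact test). Of the genes lowered in Gd6, 2334 were raised with the siRNA (1420 for independent lists, odds ratio 4.32, Fisher's exact p = 1.81e-289). Together 3149 genes changed in opposite directions and 365 in the same direction, which makes 89.6% of the genes called in both. Genes called higher in both numbered 176 (580 for independent lists) and genes called lower in both 189 (474). After median-of-ratios scaling 2243 genes changed in opposite directions, 1372 of them higher in Gd6 and 871 lower, and with a replicate block 2059 did. Genes are not independent replicates, which limits these tests. Across the 12896 genes the log2 changes of both comparisons correlated at -0.423 (Pearson) and -0.395 (Spearman).

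As a set, the 1494 genes raised in Gd6 had a median log2 change of -0.295 with the siRNA, -0.481 relative to all genes (camera p = 1.3e-43 in limma, and p = 0.000453 with an estimated correlation). The 3658 genes lowered in Gd6 had a median of 0.306, 0.12 relative to all genes (camera p = 8.67e-14 in limma, and p = 0.00871 with an estimated correlation). The rule for opposite changes named MT1F, SLCO2B1, C6, PCK1 and UGT1A6 as higher in Gd6, and CHI3L1, IFITM1, PRG4, OLFML2B and BST2 as lower in Gd6. IFITM1 values overlapped in the siRNA comparison, with 1 Gd6-Scrambled library at 1156.53 TPM and the lowest Gd6-siRNA library at 1089.6 TPM. C6 fell from 245 ± 12.8 to 77.2 ± 15.2 TPM (log2 change -1.67 ± 0.10, adjusted p = 1.44e-08) and PCK1 fell from 139 ± 19 to 64.9 ± 8.89 TPM (log2 change -1.08 ± 0.14, adjusted p = 1.38e-05) with the siRNA, while CHI3L1 rose from 4.23 ± 1.06 to 11.7 ± 2.54 TPM (log2 change 1.28 ± 0.16, adjusted p = 1.23e-05) and PRG4 rose from 37.6 ± 7.84 to 102 ± 12.5 TPM (log2 change 1.44 ± 0.13, adjusted p = 5.26e-07). Tested directly, the response to overexpression minus the response to the siRNA differed from 0 for 7375 genes, 1768 upward and 5607 downward (3066 and 2977 after median-of-ratios scaling). In that test the oxidative phosphorylation list had 73 genes higher and 0 lower of 77 tested (74 and 0 adjusted over the list alone, camera adjusted p = 4.8e-45), and adjusted p = 0.0013 with an estimated correlation. Adipocyte identity had 24 genes higher and 1 lower of 27 tested (24 and 1 adjusted over the list alone, camera adjusted p = 4.7e-21), and adjusted p = 0.012 with an estimated correlation. Unfolded protein response had 0 genes higher and 13 lower of 16 tested (0 and 14 adjusted over the list alone, camera adjusted p = 0.00014), and adjusted p = 0.01 with an estimated correlation. The interferon list had 0 genes higher and 28 lower of 29 tested (0 and 29 adjusted over the list alone, camera adjusted p = 3.3e-06), and adjusted p = 0.38 with an estimated correlation. The integrated stress response list, which rose in both comparisons, had 3 genes higher and 12 lower of 22 tested (3 and 12 adjusted over the list alone, camera adjusted p = 0.4).

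**Figure D3:**
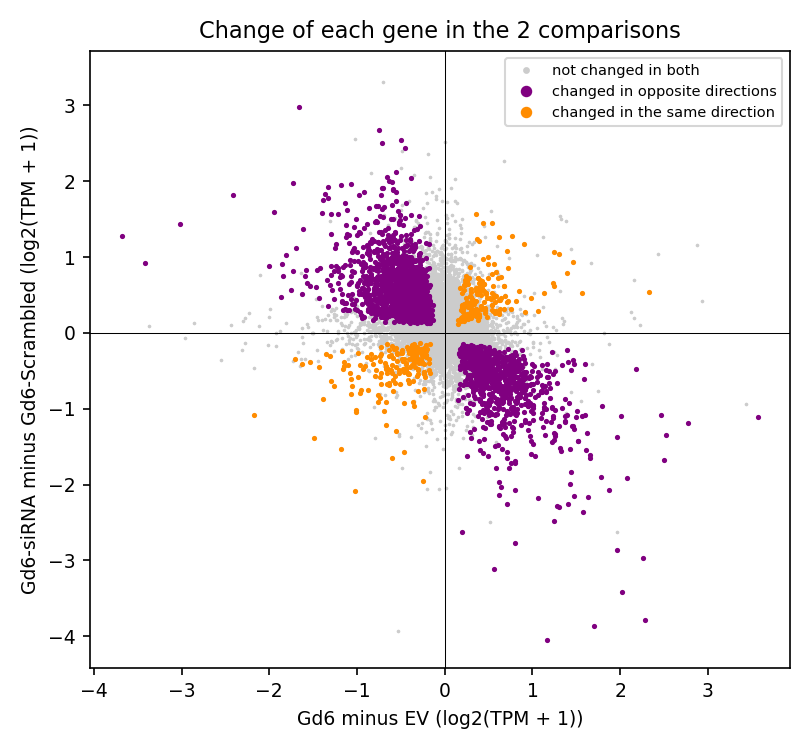
Log2 change of each tested gene in Gd6 minus EV (horizontal axis) against Gd6-siRNA minus Gd6-Scrambled (vertical axis), each point 1 gene, with 3149 genes changed in opposite directions in purple, 365 changed in the same direction in orange and all others in grey. Most coloured points lie in the upper left and lower right.

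Gd6-Scrambled and Gd6 both carry the Gd6 label and differ in the labels by the scrambled siRNA, so this comparison shows what differs with the control treatment itself or with its separate culture. Interferon-induced genes were far higher in Gd6-Scrambled, and oxidative phosphorylation genes were lower, although the interferon list lost its call with an estimated correlation (adjusted p = 0.077). IFITM1 rose from 9.41 ± 2.08 to 705 ± 306 TPM (log2 change 6.02 ± 0.28, adjusted p = 7.79e-09). MX1 rose from 5.41 ± 1.94 to 263 ± 69.5 TPM (log2 change 5.38 ± 0.33, adjusted p = 3.97e-08). All 29 type I interferon response genes rose. Over all genes tested, 3835 rose and 519 fell, 237 and 9 of them at least 2-fold.

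For the type I interferon response, 29 of 29 tested genes rose, 0 fell and 0 were not called (29 and 0 adjusted over the list alone). Interferon genes had a median of 3.07 (camera adjusted p = 1.3e-33, and 0.077 with an estimated correlation). OAS3, a sensor of double-stranded RNA, rose from 3 ± 0.795 to 85.1 ± 20.2 TPM (log2 change 4.42 ± 0.22, adjusted p = 1.15e-08). In the inflammatory (NF-kB) list, 19 of 22 tested genes rose, 0 fell and 3 were not called (20 and 0 adjusted over the list alone). Inflammatory genes had a median of 0.50 (camera adjusted p = 5.1e-08, and 0.086 with an estimated correlation). SOD2, mitochondrial superoxide dismutase, rose from 173 ± 19.8 to 448 ± 32.1 TPM (log2 change 1.37 ± 0.089, adjusted p = 6.17e-08). Unfolded protein response genes rose, as 12 of 16 tested did, 0 fell and 4 were not called (12 and 0 adjusted over the list alone). The list had a median of 0.25 (camera adjusted p = 9.2e-05, and 0.012 with an estimated correlation). HSPA5 rose from 251 ± 7.62 to 384 ± 20.8 TPM (log2 change 0.61 ± 0.053, adjusted p = 1.14e-06). For the NRF2 antioxidant response, 12 of 17 tested genes rose, 1 fell and 4 were not called (13 and 1 adjusted over the list alone). NRF2 genes had a median of 0.19 (camera adjusted p = 0.0093, and 0.091 with an estimated correlation). Of the collagen and extracellular matrix list, 18 of 31 tested genes rose, 0 fell and 13 were not called (19 and 1 adjusted over the list alone). Matrix genes had a median of 0.06 (camera adjusted p = 0.031, and 0.46 with an estimated correlation). MMP2 rose from 426 ± 29 to 886 ± 52.2 TPM (log2 change 1.06 ± 0.059, adjusted p = 1.68e-08). That list's call ended without Gd6 replicate 2 (adjusted p = 0.088), without Gd6-Scrambled replicate 3 (adjusted p = 0.059), at a mean TPM of at least 5 (adjusted p = 0.055), with only the groups compared (adjusted p = 0.12), without trend (adjusted p = 0.052), with array weights (adjusted p = 0.11) and after median-of-ratios scaling (0.03, adjusted p = 0.13). After quantile normalization it was called with a larger median of 0.37 (adjusted p = 7.8e-06).

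Oxidative phosphorylation genes fell, as 34 of 77 tested did, 0 rose and 43 were not called (36 fell and 0 rose adjusted over the list alone). Oxidative phosphorylation genes had a median of -0.40 (camera adjusted p = 8.6e-31, and 0.0068 with an estimated correlation). COX4I1 fell from 1222 ± 56 to 880 ± 33.7 TPM (log2 change -0.47 ± 0.061, adjusted p = 5.24e-05). In the fatty acid oxidation list, 3 of 24 tested genes rose, 11 fell and 10 were not called (3 and 14 adjusted over the list alone). Oxidation genes had a median of -0.39 (camera adjusted p = 6e-09, and 0.077 with an estimated correlation). Of the tricarboxylic acid cycle and pyruvate list, 0 of 25 tested genes rose, 7 fell and 18 were not called (0 and 7 adjusted over the list alone). Cycle genes had a median of -0.32 (camera adjusted p = 1e-09, and 0.091 with an estimated correlation). For adipocyte identity, 2 of 27 tested genes rose, 8 fell and 17 were not called (2 and 9 adjusted over the list alone). Adipocyte identity genes had a median of -0.31 (camera adjusted p = 8.4e-07, and 0.19 with an estimated correlation), a call that ended after quantile normalization (adjusted p = 0.075). For lipolysis and lipid droplet genes, 1 of 24 tested genes rose, 4 fell and 19 were not called (1 and 4 adjusted over the list alone). Lipolysis genes had a median of -0.23 (camera adjusted p = 9.2e-05, and 0.11 with an estimated correlation), and this too ended after quantile normalization (adjusted p = 0.054). For fatty acid and triglyceride synthesis, 4 of 22 tested genes rose, 3 fell and 15 were not called (4 and 3 adjusted over the list alone). Synthesis genes had a median of -0.17 (camera adjusted p = 0.015, and 0.42 with an estimated correlation), while their plain median was 0.01 and their mean -0.01, and they had no call after quantile normalization (adjusted p = 0.72). In glycolysis and glucose uptake, 4 of 23 tested genes rose, 4 fell and 15 were not called (4 and 4 adjusted over the list alone). Glycolysis genes had a median of -0.21 (camera adjusted p = 0.0032, and 0.39 with an estimated correlation), and the call ended without Gd6 replicate 4 (adjusted p = 0.069) and after quantile normalization (adjusted p = 0.15).

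The other lists had no call. Thermogenic genes had 6 genes higher and 0 lower of 15 tested (6 and 0 adjusted over the list alone, camera adjusted p = 0.38), and cAMP and CREB-responsive genes had 10 genes higher and 1 lower of 19 tested (10 and 1 adjusted over the list alone, camera adjusted p = 0.066). Cholesterol synthesis had 6 genes higher and 2 lower of 25 tested (7 and 2 adjusted over the list alone, camera adjusted p = 0.51). Mitochondrial biogenesis and dynamics had 5 genes higher and 2 lower of 25 tested (5 and 2 adjusted over the list alone, camera adjusted p = 0.29) and insulin signalling had 3 genes higher and 3 lower of 21 tested (3 and 3 adjusted over the list alone, camera adjusted p = 0.066). Progenitor and fibroblast genes had 8 genes higher and 1 lower of 18 tested (8 and 1 adjusted over the list alone, camera adjusted p = 0.4), although DPP4, a marker of adipose progenitors, rose from 12.7 ± 2.65 to 44.1 ± 3.63 TPM (log2 change 1.73 ± 0.12, adjusted p = 1.7e-07). Smooth muscle had 5 genes higher and 4 lower of 17 tested (5 and 4 adjusted over the list alone, camera adjusted p = 0.24). Endothelial cell genes had 1 gene higher and 0 lower of 2 tested (2 and 0 adjusted over the list alone, camera adjusted p = 0.4). Macrophage and leukocyte genes had 2 genes higher and 0 lower of 4 tested (2 and 0 adjusted over the list alone, camera adjusted p = 0.081). Integrated stress response had 10 genes higher and 0 lower of 22 tested (10 and 0 adjusted over the list alone, camera adjusted p = 0.24), and p53 response had 7 genes higher and 0 lower of 17 tested (8 and 1 adjusted over the list alone, camera adjusted p = 0.51). Cell cycle had 10 genes higher and 0 lower of 22 tested (12 and 0 adjusted over the list alone, camera adjusted p = 0.066). Hypoxia response had 5 genes higher and 1 lower of 16 tested (5 and 1 adjusted over the list alone, camera adjusted p = 0.8), and small RNA silencing machinery had 8 genes higher and 0 lower of 12 tested (8 and 0 adjusted over the list alone, camera adjusted p = 0.066). Genes next to LINC00473 had 0 genes higher and 0 lower of 3 tested (0 and 0 adjusted over the list alone, camera adjusted p = 0.4). After median-of-ratios scaling calls were gained by the cAMP list (higher, adjusted p = 0.0096, and 0.047 after quantile normalization), the macrophage and leukocyte list (higher, 0.015, and 0.034 after quantile normalization), cell cycle (higher, 0.0096), insulin signalling and mitochondrial biogenesis (both lower, each 0.037). Cell cycle was also called without a filter (0.011), at a mean TPM of at least 5 (0.041), without trend (0.042) and with a replicate block (0.049), the cAMP list without a filter (0.0067), and small RNA silencing without a filter (0.0067) and with array weights (0.042). Leaving out 1 library gave a call to insulin signalling (without Gd6 replicate 3, adjusted p = 0.045, without Gd6 replicate 4, adjusted p = 0.05, and without Gd6-Scrambled replicate 2, adjusted p = 0.034) and to macrophage and leukocyte genes (without Gd6-Scrambled replicate 2, adjusted p = 0.046). It also gave a call to cell cycle (without Gd6 replicate 3, adjusted p = 0.016, without Gd6-Scrambled replicate 1, adjusted p = 0.047, and without Gd6-Scrambled replicate 2, adjusted p = 0.034) and to small RNA silencing (without Gd6 replicate 3, adjusted p = 0.034).

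Members in counts of 5 or fewer, named after their values were seen, included LPL and ADIPOR2 (adipocyte identity), PLIN2 (lipolysis), ELOVL6, FADS1, FADS2 and LPIN1 (synthesis), CPT1A, CPT1B and PPARA (oxidation) and SLC2A3, HK1, ENO2 and PKM (glycolysis), which rose. LIPE, G0S2, CIDEC and FITM2 (lipolysis), DGAT2, GPAM and GPD1 (synthesis), PFKM, ALDOC, GAPDH and LDHB (glycolysis) and TALDO1 (NRF2) fell. In lists without a call, PPARGC1B, C10orf2, MFN2, TOMM40 and VDAC1 (biogenesis), INSR, PTPN1 and PHLDA3 (insulin), MYL9, TGFB1I1, VCL, FLNA and ACTN1 (smooth muscle), EGFL7 (endothelial), CD68 and CD74 (leukocyte) and VEGFA, CA12, ADM, P4HA2 and KDM3A (hypoxia) rose. BDNF (cAMP), FDPS and TM7SF2 (cholesterol), FIS1 and PHB2 (biogenesis), GRB14, IGFBP3 and IGFBP5 (insulin), CD34 (progenitor), TAGLN, LMOD1, CYR61 and CTGF (smooth muscle) and NDRG1 (hypoxia) fell. Of the genes that rose, LPL, PLIN2, LPIN1, CPT1A, CPT1B, SLC2A3, ACTN1, CD68, CD74, CA12 and KDM3A were called under both median-of-ratios scaling and quantile normalization, and the others lost their call under 1 or both. Of those that fell, G0S2, CIDEC, DGAT2, GPAM, GPD1 and GAPDH were not called after quantile normalization. The direction turned in GPD1 (0.02) and INSR (-0.01) after quantile normalization and in MFN2 and VDAC1 (each -0.04) after median-of-ratios scaling.

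After IFITM1 and MX1, the largest rises were in IFI27, IFI44L and BST2, all interferon-induced, of which BST2 rose from 2.5 ± 0.994 to 98.8 ± 31.7 TPM (log2 change 4.83 ± 0.27, adjusted p = 1.6e-08). The largest falls were in DIRC3, CTGF, S100B, ACSM3 and CFD. The long non-coding RNA DIRC3 fell from 12.1 ± 1.9 to 2.81 ± 0.253 TPM (log2 change -1.77 ± 0.13, adjusted p = 1.7e-07), and CFD, the adipocyte protease adipsin, fell from 1094 ± 189 to 541 ± 125 TPM (log2 change -1.03 ± 0.26, adjusted p = 0.00691). Each of these 10 genes had group values that did not overlap, as did 5239 of the tested genes (40.6%, where chance gives 5.71%). The median change of all genes was 0.178, and after median-of-ratios scaling it was -0.012 and the count of changed genes was 2620, with 1122 higher and 1498 lower (1084 and 1182 after quantile normalization). Given in the same way, the members higher/lower after these 2 scalings were 1/14 and 2/5 (adipocyte identity), 4/1 and 3/1 (cAMP), 1/11 and 1/4 (lipolysis), 1/10 and 2/1 (synthesis), 4/6 and 4/4 (cholesterol), 2/18 and 2/15 (fatty acid oxidation), 0/56 and 0/39 (oxidative phosphorylation), 0/18 and 0/15 (tricarboxylic acid cycle), 0/6 and 0/5 (biogenesis), 1/13 and 2/6 (glycolysis), 0/7 and 0/5 (insulin), 14/9 and 17/2 (matrix), 1/5 and 2/5 (smooth muscle), 1/0 and 0/0 (endothelial), 15/0 and 11/0 (inflammatory), 6/0 and 7/0 (unfolded protein response), 3/2 and 5/2 (integrated stress response), 4/1 and 3/1 (cell cycle), 2/6 and 3/2 (hypoxia), 4/2 and 9/1 (NRF2) and 1/0 and 0/0 (small RNA silencing).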

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

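Among the tests below, those of the interferon genes against leukocyte RNA, of the oxidative phosphorylation genes against gene length and GC content and against fewer adipocytes, and of other splits of the samples except those that keep the siRNA groups were set before their results were seen. The others were chosen after the result was seen.

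A value was singled out where the highest or lowest of 4 libraries of a group lay apart, by a gap to the nearest other that exceeded Dixon's critical share of the group's range. This held for 11 of 229 gene values and 3 of 81 list levels, and chance alone gives about 1 in 20. These counts leave out MIR616, given below, which was named because it stood apart. EV replicate 1 was highest in SLC25A18 (6.83 TPM against 4.26 to 4.45, ratio 0.926). EV replicate 2 was highest in MIR616 (7.39 TPM against 0, ratio 1). EV replicate 4 was lowest in HMOX1 (239 TPM against 256 to 260, ratio 0.832). Gd6-Scrambled replicate 2 was lowest in the macrophage and leukocyte list (3.45 against 3.73 to 3.75, ratio 0.95). Gd6-Scrambled replicate 3 was highest in MIR616 (7.25 TPM against 0, ratio 1). Gd6-Scrambled replicate 3 was lowest in the NRF2 antioxidant response list (7.37 against 7.48 to 7.49, ratio 0.949). Gd6-Scrambled replicate 4 was lowest in CIDEC (2100 TPM against 2290 to 2320, ratio 0.868), HERPUD1 (52.2 TPM against 54.2 to 54.4, ratio 0.883) and LIPE (503 TPM against 587 to 594, ratio 0.923). Gd6-siRNA replicate 1 was highest in BST2 (218 TPM against 161 to 170, ratio 0.842). Gd6-siRNA replicate 1 was lowest in RBP4 (7.12 TPM against 13.5 to 14.7, ratio 0.837). Gd6-siRNA replicate 2 was highest in COX4I1 (559 TPM against 549, ratio 0.966) and TRIB3 (154 TPM against 136 to 139, ratio 0.869). Gd6-siRNA replicate 3 was highest in the cell cycle list (3.06 against 2.86 to 2.89, ratio 0.838). Gd6-siRNA replicate 3 was lowest in PDHA1 (72.7 TPM against 79.8 to 80.1, ratio 0.955). List levels are means of log2(TPM + 1).

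LINC00473 in Gd6-Scrambled stood apart, with replicate 3 at 245 TPM and the others between 2.85 and 3.19 TPM (gap over range 0.999). A mislabelled or mixed library of this series was tested by the highest LINC00473 value elsewhere, which was 4.23 TPM, and by correlation, which was higher with its own group (0.9896) than with any other (0.9786), and both argue against it. Signalling through cAMP or CREB in that culture was tested by the cAMP list, where 0 of 19 members were at least 2-fold above the rest of the group, which argues against it. More vector, or more expression from it, remains open, since the table has no entry for the vector, and 1 other gene (MIR616, 7.25 TPM, named after its value was seen) was at least 10 times above the rest of the group, against up to 26 genes in other libraries. No other biological explanation was tested.

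Mitochondrial and adipocyte genes were higher in Gd6 than in EV and lower in Gd6-siRNA than in Gd6-Scrambled. Rescaling of TPM as the whole cause is argued against by the members called after median-of-ratios scaling, which were 69 higher in Gd6 and 76 lower with the siRNA of 77 oxidative phosphorylation genes (medians 0.66 and -0.76) and 21 and 26 of 27 adipocyte identity genes (medians 0.78 and -1.03). Gene length and GC content are argued against for the oxidative phosphorylation and the adipocyte identity list by 0 of 1000 random lists each, matched on level, length and GC content, that reached the list's medians, with 100% of the genes having values. Fewer adipocytes with more of any other cell type in Gd6-siRNA remain open. The progenitor list rose by 0.53 (log2, SE 0.09) more than the smooth muscle list, whose members went both ways, so this cannot decide. A response to LINC00473, which the groups name, may underlie the pattern as a hypothesis, but it was found and tested on these data only and the labels do not exclude a separate culture per group.

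Type I interferon genes were lower in Gd6 than in EV and higher in Gd6-Scrambled than in Gd6. RNA from leukocytes is argued against by 7 leukocyte genes, of which the highest mean in Gd6-Scrambled was 0.87 TPM (C1QA). The macrophage and leukocyte list, of which 4 genes were tested, was called higher in Gd6-Scrambled than in Gd6 after median-of-ratios scaling (adjusted p = 0.015) and quantile normalization (adjusted p = 0.034), with CD68 and CD74 higher, and the source of these 2 was not tested. The amount of LINC00473 as the cause of the difference between Gd6-Scrambled and Gd6 is argued against by a gap of 2.84 (log2) between the lowest Gd6-Scrambled and the highest Gd6 library in the list's level, at median LINC00473 values of 3.12 and 3.04 TPM. Transfection and a separate culture cannot be told apart, as both siRNA groups share the raised level, with Gd6-siRNA 0.16 above Gd6-Scrambled and Gd6-Scrambled 3.35 above Gd6, and the design changes both at once. The lower level in Gd6 than in EV, where LINC00473 differs, was not tested further.

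Other splits of the same samples into groups of the same sizes were counted for each total. For Gd6 against EV 1 of 35 splits, the real one with 5152 genes, gave a count as large, and the highest other split gave 2590 genes. For the siRNA comparison it was 1 of 35 (6679 genes, highest other 1), for Gd6-Scrambled against Gd6 1 of 35 (4354 genes, highest other 1809), for the difference between the comparisons 1 of 100 drawn splits (7375 genes, highest other 3743) and for genes changed in opposite directions 1 of 100 (3149 genes, highest other 0). Most drawn splits mix the siRNA groups, which leaves few calls to share, so this last count was repeated with the siRNA groups kept (4872 to 5986 calls in the other splits), where it was 1 of 35 splits of EV and Gd6 (highest other 162). As mixed splits widen the spread and lose calls, the counts show only that the groups differ.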

How the results depend on the processing

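All alternatives were set before the data were examined, and the same direction and side of the threshold were kept by most results. Of the 359 named gene results, 329 were unchanged under median-of-ratios scaling and 324 under quantile normalization, where 28 and 33 lost their call, 1 and 1 gained one and 1 and 1 reversed. For 81 list results, 74 were unchanged under median-of-ratios scaling (1 lost, 6 gained), 73 under quantile normalization (5 lost, 3 gained) and 54 with an estimated correlation (27 lost). Leaving out 1 library ended 10 and gave 6 calls among 5385 gene results, and ended 5 and gave 9 among 1215 list results. Under the pseudocounts, filters, no trend, array weights, fits of the groups compared and the replicate block, at most 5 gene results and 8 list results changed in each. GPD1 in Gd6-Scrambled against Gd6 reversed to 0.02 under quantile normalization, and MFN2 in that comparison reversed to -0.04 under median-of-ratios scaling. The cause was not tested.

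For Gd6-Scrambled against Gd6 the 4354 changed genes became 2620 under median-of-ratios scaling and 2266 under quantile normalization, both of which remove by construction a shift common to all genes. Genes changed in opposite directions numbered 2059 with a replicate block against 3149, and the cause was not tested. Fixed lists called with an estimated correlation numbered 8 for Gd6 against EV (16 with the preset), 7 for the siRNA comparison (16) and 2 for Gd6-Scrambled against Gd6 (12), since correlated genes count for less by construction.

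LINC00473 from EV to Gd6 passed the threshold at a pseudocount of 0.1 (4.89, adjusted p = 0.0031), with only the groups compared (1.97, adjusted p = 0.00015) and without Gd6-Scrambled replicate 3 (1.97, adjusted p = 2.3e-06), with 1.76 to 2.2 over the libraries left out, as the wide Gd6-Scrambled group then no longer sets the spread in the latter cases. With the siRNA LINC00473 lost its call at a pseudocount of 5 (-1.7, adjusted p = 0.09), without a filter (-2.62, adjusted p = 0.063), with only the groups compared (-2.62, adjusted p = 0.11), with array weights (-2.03, adjusted p = 0.09) and with a replicate block (-2.62, adjusted p = 0.06), and it ranged from -3.14 to -1.14 over the libraries left out. The cause was not tested.

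The fit of only the groups compared was not run for the difference between comparisons, which needs all 4 groups. No protocol pairs the replicate numbers. Deviations from the group mean correlated between libraries of the same number at -0.195, -0.0997 and -0.0607 for EV and Gd6 and at -0.118, -0.412, -0.335 and -0.28 for the siRNA groups, which gives no sign of pairs, but at 0.421, 0.235 and 0.0746 for Gd6 and Gd6-Scrambled, where a shared factor remains open. With a replicate block that comparison had 3751 changed genes, and its cell cycle list gained a call (adjusted p = 0.049). Depth is unknown, which leaves the counting error of genes at a few TPM unknown, LINC00473 among them.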

Other observations

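The tests of LINC00473 amount in this part were chosen after the result was seen.

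Adipocyte identity and oxidative phosphorylation genes were lower in Gd6-siRNA than in the empty-vector cells, not only lower than in Gd6-Scrambled. The mean log2(TPM + 1) of the adipocyte identity list was 8.5 ± 0.057 in EV (n = 4), 9.11 ± 0.062 in Gd6 (n = 3), 8.97 ± 0.092 in Gd6-Scrambled (n = 4) and 8.02 ± 0.123 in Gd6-siRNA (n = 4). ADIPOQ stood at 3407 ± 295 TPM in EV and 1193 ± 207 TPM in Gd6-siRNA. If the amount of LINC00473 alone set these levels, and more of it never lowered them, Gd6-siRNA would not lie below EV. The lowest LINC00473 value in Gd6-siRNA was 0.56 TPM, and in EV it is listed at 0. Every Gd6-siRNA library lay below every EV library, by at least 0.19 for oxidative phosphorylation and 0.25 for adipocyte identity, which argues against that hypothesis. An equal effect of transfection added to the amount of LINC00473 requires that the rise from EV to Gd6 and the change with the siRNA do not sum below 0. The sum was -0.33 (SE 0.09) for adipocyte identity, which argues against it, and -0.03 (SE 0.04) for oxidative phosphorylation, where it remains open. After median-of-ratios scaling the sums were -0.4 (SE 0.08) and -0.1 (SE 0.09), and after quantile normalization -0.35 (SE 0.09) and -0.06 (SE 0.05). A further siRNA effect may add to that of LINC00473, and no group separates them.

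Some genes and lists did not reverse. The integrated stress response level was 5.27, 5.6, 5.91 and 6.71 in EV, Gd6, Gd6-Scrambled and Gd6-siRNA. There LPL was 23.6 ± 0.493, 11.3 ± 0.709, 19.4 ± 2.68 and 16.8 ± 2.77 TPM. The unfolded protein response (6.09, 5.7, 6.12 and 6.63), cAMP, inflammatory and interferon levels, lower in Gd6, were not below EV in Gd6-Scrambled. UCP1 was 1.57 ± 0.194 TPM in Gd6-Scrambled and 1.1 ± 0.631 TPM in Gd6-siRNA (log2 change -0.34 ± 0.26, adjusted p = 0.292).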
